A study of Caenorhabditis elegans with 24 samples.

How the data were processed

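RNA from wild-type N2 Caenorhabditis elegans was labelled with Cy3 or Cy5 and hybridised to Agilent 2-colour expression arrays, per the labels' protocols. There were 24 samples on 12 arrays of 3 slides. Of these, 12 samples came from K-medium, a salt solution that served as negative control, and 4 came from each of 0.2, 2 and 20 µM juglone, after 24 h in darkness without added food. Every group held Cy3 and Cy5 samples in equal numbers. Each array carried 1 juglone sample and 1 control sample of opposite dye, as taken from the file names and tested on the spot positions that tables of 1 array share. The labels do not say that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical.

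The deposited spot tables hold intensity per spot (mean foreground, median local background and background SD) for 45220 spots per array, quantified with ImaGene 8.0.0 per the file headers, with no background subtraction in the signal columns. A second deposited table holds log2 values per transcript name, centred on a median of 0 for each transcript. How the authors made it is not given in the sources used here, and its scale before centring stays unknown. Each of its columns correlated best with the centred scanner values of its own sample, in 24 of 24 samples, with rank correlations across genes from 0.373 to 0.786. Column medians lay between -0.08 and 0.19. This table was used as an alternative.

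From the intensities, background was corrected by normexp with an offset of 50, and log2 values were quantile normalized over the 24 samples. Control spots were left out after background correction, as were 29 spots marked in the files, and spots of 1 probe were averaged. A probe was tested where its foreground exceeded the local background by 2.6 background SDs in at least 4 samples, which left 43206 probes and set aside 369. The offset compresses fold changes of dim probes. Where a called probe exceeded the 95th percentile of the negative control spots in no sample of the dimmer group, its fold is given as a lower bound. The bound sets the brighter group's mean against the mean, over the dimmer group's samples, of the higher of the probe's own value and the normalized value at that percentile. Of 43603 probes, 35479 were assigned to 1 gene, 1313 to several and 6811 to none through the reference gene table, the WBcel235 RefSeq annotation. That table was used for names alone, and no coordinates are given. For the deposited log2 table, 15993 transcript names had 1 gene symbol in the platform annotation, which does not list 10145 others.

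Differences were tested with limma 3.58.1 in R 4.3.3 on all 24 samples. Group and dye were fixed terms and the array was a random block (correlation 0.114, statmod 1.5.0). P-values covered both directions, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Total degrees of freedom were 22.1, of which 3.13 came from the prior. The dose trend coded the groups 0, 1, 2 and 3. Gene lists were 44 sets, tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, each adjusted over 132 tests.

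A gene with several probes was represented in the lists by the probe with the highest mean intensity, taken from probes of that gene alone where there was such a probe, and no called gene had probes called in opposite directions. For each dose, the genes named were those alone on their probe, with an adjusted p under 0.05 and all 4 juglone samples on 1 side of their own-array controls, up to 10 rises and 10 falls by size. Where none passed, the 3 rises and 3 falls with the smallest p were given as values. Up to 4 passing members per list, or the 1 with the smallest p where none passed, gst-4, gcs-1, sod-3, hsp-16.2, mtl-1, ctl-1, skn-1, daf-16 and vit-2 in every case, and up to 5 rises and 5 falls per dose contrast completed the rule. The groups, designs, lists, naming rule and most alternatives were fixed before the data were examined.

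Simulated data on the 43206 real probes, with 100 probes changed 2-fold and 100 changed 4-fold at 20 µM, gave back 72% of the former and 100% of the latter, with 12 false calls. That simulation drew the 12 controls as independent and gave all groups the same SD for a probe. Over probes with a mean log2 above 8 the real median SD was 0.33 in the 12 controls and 0.75 at 20 µM. The share of 72% may therefore be too high for these data. Alternatives covered background correction, normalization, filters, dye, array and slide terms, control choice, dye subsets, each sample left out, the deposited log2 table, variance models and thresholds. The alternatives that average control sets, leave out samples that stand apart, filter on the negative controls, add residual components or fit the 0.2 and 20 µM samples alone were chosen after seeing the data.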

Results

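Expression was measured in age-synchronized adult wild-type nematodes after 24 h in juglone, a naphthoquinone that cycles redox in cells, at 0.2, 2 or 20 µM (n = 4 samples each), or in K-medium alone (n = 12). The series title uses juglone as a positive control compound, one that brings about oxidative stress, and the comparisons ask which genes differ from control at each dose and between doses. Median foreground intensity ranged from 6.10 to 251.0 across samples, and between 28.4% and 55.4% of probes exceeded the 95th percentile of the 153 negative control spots. The number of arrays limits the precision.

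The controls fell into sets of 9 and 3 near-identical samples. Over the 8861 brighter probes, pairs within the set of 9 differed by a median absolute deviation of log2 differences of 0.20 to 0.44, and pairs within the set of 3 by 0.28 to 0.30. Spots of 1 probe within an array had an SD of 0.14 to 0.34, which gives 0.20 to 0.48 for a difference of 2 spots, so controls within a set differed by no more than replicate spots. Between the sets the differences were 0.69 to 0.79. The 3 were the Cy3 controls of slide 2, and the Cy5 control of that slide lay in the set of 9. Juglone samples of 1 dose differed by 0.61 to 1.94 (median 0.958), and those of different doses by 0.35 to 1.93 (median 0.785). Some of the latter lay within the range of replicate spots, at 0.35 for 0.2 and 20 µM replicates 1, 0.37 for 0.2 and 20 µM replicates 4 and 0.43 for 0.2 µM replicate 1 and 2 µM replicate 2. The 0.2 and 20 µM samples of each replicate number shared a slide and a dye, and their deviations from the dose means correlated at 0.488, 0.730, 0.242 and 0.601 across probes. The design fixed before the data were examined counts the 12 controls as independent samples. Its counts are given with those found when each control set was averaged and counted as 1 sample.

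At 20 µM, single genes of detoxification families, and 3 antimicrobial peptide genes or their relatives, rose against controls. The probe shared by K08F4.13 and gst-4, a glutathione S-transferase used as a reporter of oxidative stress, rose by 4.09 ± 0.67 on the log2 scale (SE, limma adjusted p = 0.0041), and this probe does not separate those genes. ZK742.4 rose by 3.98 ± 0.56 (SE), W06H8.2 by 3.39 ± 0.34, F18E3.12 by 2.75 ± 0.36 and M03A1.8 by 2.19 ± 0.29, and F56D5.3 was at least 4.18-fold higher (adjusted p = 0.00028). The glucuronosyltransferase gene ugt-13 rose by 2.71 ± 0.30 and the short-chain dehydrogenase gene dhs-8 by 2.71 ± 0.33. Among antimicrobial peptide genes and their relatives, cnc-4 rose by 3.25 ± 0.53, fipr-26 by 2.65 ± 0.45 and fipr-22 by 2.29 ± 0.26. The histone gene his-17 fell by 1.16 ± 0.20. Apart from the shared gst-4 probe, the naming rule required all 4 juglone samples to lie on the same side of their own-array controls. It was therefore fixed in advance that these genes were higher, and his-17 lower, in 4 of 4. The shared gst-4 probe was also higher in 4 of 4. Histone genes have near-identical copies, and 5 of 5 his-17 probes passed, so which copies were measured is uncertain. In controls W06H8.2 exceeded the negative controls in 4 of 12 samples, and the intensity offset compresses its fold. F56D5.3 exceeded them in 0 of 12, so its fold has only a lower bound.

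In all, 80 of 43206 probes passed at 20 µM, 75 higher and 5 lower, for 55 and 1 genes. No probe passed when each control set was averaged to 1 sample (286 at an unadjusted p under 0.05 in limma), when the dose was set against its own 4 array-mate controls (1506) or with the array as a fixed block (1856). All 80 had an unadjusted p under 0.05 in limma in each of these fits, which reuse the same samples. With averaged sets all 80 kept their direction, with a median fold ratio of 0.965 and a median SE 1.90 times as large. Averaging leaves 2 control samples in place of 12, which by itself makes calls harder to reach. With 75th percentile scaling, which moved the median of all probes by 0.15, 0.47 and 0.14 at 0.2, 2 and 20 µM, the split was 89 higher and 0 lower. With loess it was 100 higher and 25 lower. Among named genes with several probes, 3 of 5 passed for ZK742.4, 5 of 7 for fipr-22, 1 of 6 for gsto-2 and 1 of 2 each for numr-1 and catp-3, with all probes of each gene in 1 direction, while for nspe-1 5 of 11 passed and 9 of 11 were higher. The count was 251 without juglone 20 µM replicate 4, 48 without replicate 1 and 44 without replicate 2.

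Targets of SKN-1, the transcription factor that drives the oxidative stress response, were higher at 20 µM as a list. Of 22 SKN-1 and phase II target genes 12 rose (13 adjusted over the list alone), none fell, and the median log2 fold was 0.93 (camera adjusted p = 0.00067 with an estimated correlation). Members that rose included ugt-13 and dhs-8, gst-30 at 3.22 ± 0.40 (SE; higher in 3 of 4 juglone samples than on the same array) and ugt-11, which exceeded the negative controls in 0 of 12 controls and was at least 1.68-fold higher (adjusted p = 0.0013). The list's mean log2 intensity per sample was 9.58 ± 0.51 (SD, n = 4) at 20 µM, 8.43 ± 0.17 (SD, n = 4) at 2 µM, 8.28 ± 0.15 (SD, n = 4) at 0.2 µM and 8.36 ± 0.14 (SD, n = 12) in controls. It was 8.29 over the set of 9 controls and 8.57 over the set of 3. Against controls of the same slide the list's median fold at 20 µM was 1.12 on slide 1 (n = 2 juglone samples), 0.43 on slide 2 (n = 1) and 1.23 on slide 3 (n = 1). Of the 4 controls of slide 2, 3 form the smaller control set. Medians given for slide 2, here and below, thus rest mainly on that set. With an estimated correlation the list passed in 42 of 48 alternatives, in which the adjusted p ranged from 3.9e-05 to 0.63. It did not pass with averaged control sets (adjusted p = 0.084, and adjusted p = 0.15 also without juglone 2 µM replicate 4), own-array controls (adjusted p = 0.63), the Cy5 samples alone (adjusted p = 0.32), probes above background in all 24 samples (adjusted p = 0.41) or without the 6 samples that stood apart (adjusted p = 0.051). Its median was 2.00 in the deposited log2 table.

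**Figure D1:**
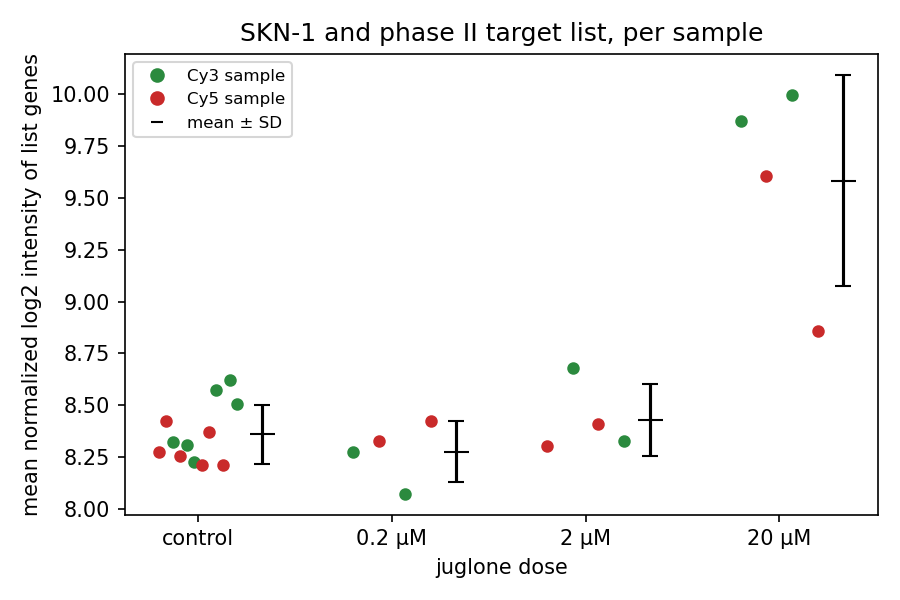
Mean normalized log2 intensity of the 22 SKN-1 and phase II target genes (vertical axis) in each sample by juglone dose (horizontal axis). Points are samples coloured by dye and bars are mean ± SD; the 4 samples at 20 µM lie between 8.86 and 10.0, above the 12 controls, which lie between 8.21 and 8.62.

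The families of conjugating enzymes overlap that list. Of 49 glutathione S-transferases 8 rose (13 adjusted over the list alone), and 6 of the 8 are also SKN-1 list members. Among the 8 were gsto-2, outside the SKN-1 list, at 1.95 ± 0.21 (SE) and gst-13, inside it, at 1.75 ± 0.26. The median of the 49 genes was 0.22. Of 67 UDP-glucuronosyltransferases 3 rose (12 adjusted over the list alone), and 2 of the 3 are also SKN-1 list members. The gene outside the SKN-1 list was ugt-64, at 1.39 ± 0.18. The median of the 67 genes was 0.15. Both lists passed camera at the preset correlation and did not pass with an estimated one (adjusted p = 0.16 for the transferases and adjusted p = 0.12 for the glucuronosyltransferases). On slides 1, 2 and 3 the medians were 0.17, 0.20 and 0.55 for the transferases and 0.32, 0.03 and 0.02 for the glucuronosyltransferases. Without juglone 20 µM replicate 1 the transferase median was 0.092, and without the 6 samples that stood apart it was 0.13. It was 0.33 with 75th percentile scaling, which also raised the median of all probes at 20 µM. Over probes above background in all 24 samples, a filter that left fewer probes, it was 0.34. For the glucuronosyltransferases it was 0.081 without those 6 samples, 0.090 with array weights, 0.28 with 75th percentile scaling and 0.38 in the deposited log2 table, and the list passed with an estimated correlation without 20 µM replicate 4 (adjusted p = 0.032) and with the first residual component (adjusted p = 0.0051) or the first 2 (adjusted p = 0.0097) as covariates. None of 77 cytochrome P450 genes passed, and their median was 0.02.

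Of 31 antioxidant enzymes 2 rose (3 adjusted over the list alone). These were msra-1, a methionine sulfoxide reductase, at 1.88 ± 0.33 (SE) and gsr-1, glutathione reductase, at 0.72 ± 0.13. The list as a whole did not pass (median -0.03, adjusted p = 0.43). The gsr-1 value was -0.17 in the deposited log2 table, and its call did not hold with 75th percentile scaling (adjusted p = 0.48). Of 3 gsr-1 probes 1 passed, and the others went the opposite way without passing. Of 17 metal response genes cdr-4 rose by 2.02 ± 0.37 and numr-1 was 2.14-fold higher (log2 SE 0.21), each higher in 3 of 4 juglone samples than on the same array.

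Of 107 innate immune effectors 3 rose at 20 µM (10 adjusted over the list alone), which were cnc-4, fipr-22 and fipr-26. The list median was 0.12 (adjusted p = 0.018 at the preset correlation, adjusted p = 0.49 with an estimated correlation), and it was 0.22, -0.01 and 0.07 on slides 1, 2 and 3. Its mean log2 intensity lay between 8.58 and 8.75 in the 12 controls. It reached 9.17, 9.36 and 9.58 in 1 sample each at 0.2, 2 and 20 µM (replicates 2, 3 and 2), and those samples stood apart from the other 21 on the first principal component, which held 33.3% of the variance. In the same samples muscle markers had a mean log2 intensity of 10.48, 10.21 and 10.89, against 11.22 to 12.03 in controls, and vitellogenins 10.61, 10.18 and 10.37, against 11.78 to 13.58. Other juglone samples also lay below the control ranges, with muscle markers at 10.92 in 0.2 µM replicate 3, 11.17 in 20 µM replicate 1 and 11.08 in 20 µM replicate 3, and vitellogenins at 10.67 in 0.2 µM replicate 1, 11.55 in 2 µM replicate 2 and 11.58 in 20 µM replicate 1. None of 13 osmotic stress response genes passed (4 adjusted over the list alone), with nlp-31 at 2.58 ± 0.55 (SE, adjusted p = 0.058) and a list median of 0.51 (adjusted p = 0.014 at the preset correlation, adjusted p = 0.44 with an estimated correlation). On slides 1, 2 and 3 that median was 0.85, 0.16 and 0.22. Without juglone 20 µM replicate 2 it was 0.17 and the list did not pass at the preset correlation (adjusted p = 0.089). The list's mean log2 intensity was 9.88, 10.35 and 10.56 in the samples that stood apart, 9.33 to 9.66 in the other 3 at 20 µM and at most 9.36 in controls.

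At 20 µM 12 lists, among them collagens, histones, vitellogenins, muscle and intestine markers and energy metabolism, were lower at the preset correlation, and none of them passed once the correlation was estimated. The median of 174 collagens was -0.31 (adjusted p = 0.12 with an estimated correlation), with col-45 at -0.93 ± 0.22 (SE), and -0.52, 0.08 and -0.35 on slides 1, 2 and 3. The median of 45 histones was -0.33 (adjusted p = 0.18 with an estimated correlation; 1 fell, 10 adjusted over the list alone), with -0.58, -0.29 and 0.23 on the slides in that order, and his-17 did not pass with 75th percentile scaling (adjusted p = 0.11). The median of 6 vitellogenins, the yolk proteins, was -0.89 (adjusted p = 0.49 with an estimated correlation), with -1.29, 0.50 and -1.87 on the slides. Their mean log2 intensity was 13.28 over the set of 9 controls, 11.91 over the set of 3 and 11.97 at 20 µM. In 20 µM replicate 4, the 1 sample of that dose on slide 2, it was 12.74. That lies above the set of 3 (at most 12.05) and below the set of 9 (at least 13.08). The direction in that sample thus depended on the control set.

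The other lower lists had adjusted p from 0.12 to 0.62 with an estimated correlation. The median was -0.42 for 29 muscle markers (-0.85, 0.48 and -0.72 on slides 1, 2 and 3), -0.38 for 31 trehalose, glycogen and glycolysis genes (-0.67, -0.00 and -0.13), -0.28 for 27 intestine markers (-0.59, 0.07 and -0.29) and -0.21 for 54 genes of the mitochondrial respiratory chain (-0.63, 0.10 and -0.15). Without juglone 20 µM replicate 2, which stood apart, the glycolysis median was -0.11 and that of the respiratory chain -0.04, and neither list passed at the preset correlation (adjusted p = 0.066 and adjusted p = 0.18). Medians were -0.16 for major sperm proteins, -0.14 for translation factors, -0.12 for fasting and lipid catabolism, -0.14 for ribosomal proteins, which turned to 0.02 with loess, and -0.02 for C-type lectins. Higher medians were found for 30 germline genes, at 0.26 (adjusted p = 0.49 with an estimated correlation; 0.37, 0.29 and -0.08 on slides 1, 2 and 3), and 28 genes of the DNA damage response and apoptosis, at 0.18 (adjusted p = 0.51; 0.32, 0.15 and -0.06). Of 44 lists, 19 passed at the preset correlation at 20 µM, 7 higher and 12 lower, and 1 passed with an estimated correlation.

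Other reference genes of stress responses did not pass at 20 µM. The log2 fold was 0.38 ± 0.25 (SE) for gcs-1, which makes the first step of glutathione synthesis, -0.07 ± 0.44 for the superoxide dismutase gene sod-3, -0.27 ± 0.18 for the catalase gene ctl-1 and -0.13 ± 0.56 for the small heat shock protein gene hsp-16.2. It was -0.00 ± 0.34 for the metallothionein gene mtl-1, 0.18 ± 0.23 for skn-1, -0.44 ± 0.20 for daf-16 and -0.79 ± 0.41 for the yolk protein gene vit-2.

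At 0.2 µM no probe passed in limma, with 2712 of 43206 (6.28%) at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were C02E7.6 at 0.93 ± 0.15 (SE), T24D3.2 at 0.78 ± 0.15, the serine palmitoyltransferase gene sptl-2 at 0.54 ± 0.11, the stearoyl-CoA desaturase gene fat-6 at -0.59 ± 0.12, hex-1 at -0.64 ± 0.14 and Y47H9C.14 at -0.54 ± 0.12. The first 3 were higher and the last 3 lower in 4 of 4 juglone samples than on the same array. At the preset correlation 12 of 44 lists passed, among them body wall and vulval muscle markers (median -0.66) and intestine markers (median -0.44), and 0 passed with an estimated correlation (adjusted p = 0.44 and adjusted p = 0.18 for these lists). On slides 1, 2 and 3 the medians were -1.24, 0.62 and -0.58 for muscle and -0.57, 0.22 and -0.48 for intestine markers. Muscle markers had a mean log2 intensity of 11.84 over the set of 9 controls and 11.28 over the set of 3. The shared gst-4 probe was at 0.68 ± 0.67.

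At 2 µM no probe passed in limma either, with 3313 (7.67%) at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were F21G4.5 at 0.60 ± 0.11 (SE), F38A5.2 at 0.62 ± 0.12, the insulin-like peptide gene ins-38 at 0.74 ± 0.15, Y48E1B.3 at -0.53 ± 0.11, dnsn-1 at -0.61 ± 0.13 and Y110A2AL.4 at -1.26 ± 0.28. The shared gst-4 probe was at 0.40 ± 0.67. At the preset correlation 11 lists passed, all lower, with the smallest p for oogenesis and eggshell genes (median -0.41, and -0.27 and -0.46 on slides 2 and 3, adjusted p = 0.57 with an estimated correlation), and 0 passed with an estimated correlation. Juglone 2 µM replicate 4 differed from the set of 9 controls by 0.24 to 0.35, within the 0.20 to 0.44 found among those controls. With the Cy5 samples alone, 2 of this dose, 1039 probes passed.

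**Figure D2:**
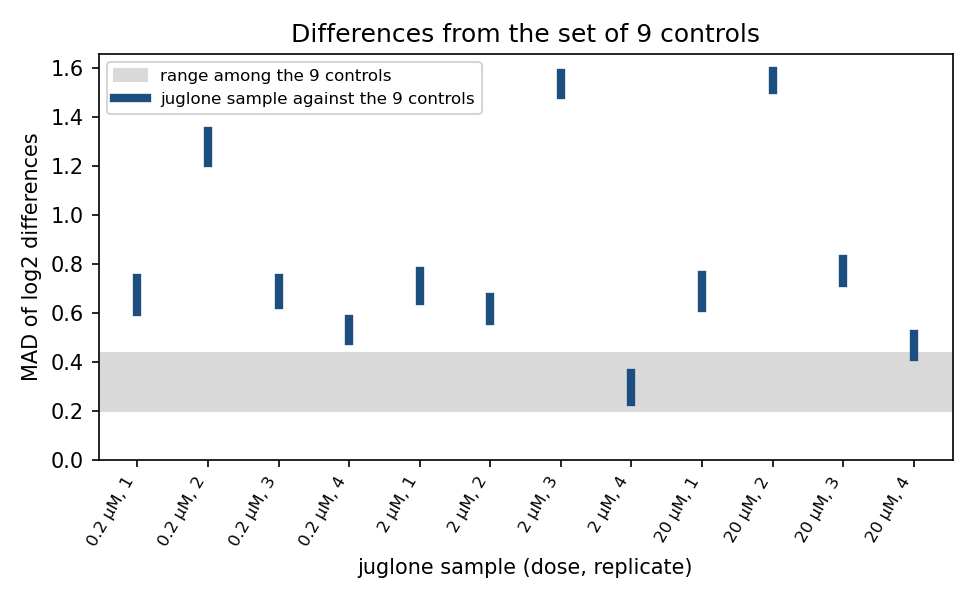
Range of the median absolute deviation of log2 differences (vertical axis) between each juglone sample (horizontal axis) and the set of 9 controls; the grey band is the range among those controls. The 2 µM replicate 4 lies within the band at 0.24 to 0.35, and 20 µM replicate 4, at 0.42 to 0.51, overlaps its upper end.

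Between doses, 17 probes of 14 genes were higher at 20 than at 2 µM, among them W06H8.2 at 3.27 ± 0.43 (SE), gst-30 at 3.11 ± 0.50 and fipr-22 at 2.23 ± 0.32, while dhs-8 was 6.04-fold higher (log2 SE 0.42) and F56D5.3, which exceeded the negative controls in 0 of 4 samples at 2 µM, was at least 3.55-fold higher (adjusted p = 0.015). Between 20 and 0.2 µM 33 probes passed, 31 of them higher, with ZK742.4 at 4.26 ± 0.70 and nspe-1 at 2.50 ± 0.44, while C02E7.6 fell by 1.32 ± 0.21. No probe passed between 2 and 0.2 µM in limma (2204 at an unadjusted p under 0.05). The dose trend called 25 probes, 23 with an upward slope. Fitted slopes per dose code were 0.94 ± 0.18 for sdz-8, 0.90 ± 0.17 for cnc-4 and 0.75 ± 0.15 for the cation-transporting ATPase gene catp-3. For his-17 the slope was downward, by 0.35 ± 0.06. A difference at 20 µM alone can give such slopes, and no probe passed at 0.2 or 2 µM against control. The trend therefore does not show a change at each step. A test of any dose called 48 probes. Each of these counts was 0 with averaged control sets. The contrasts between doses hold no control sample, but their SE rests on a spread pooled over all 24 samples, near-identical controls included. Over the brighter probes the median SD was 0.33 in the 12 controls and 0.60, 0.75 and 0.75 at 0.2, 2 and 20 µM. The SE between doses may thus be too small and the counts too high. On the 8 samples at 0.2 and 20 µM alone, no probe passed in limma, with slide and dye together as a block (2350 at an unadjusted p under 0.05) or without it (805). The SKN-1 list mean was higher at 20 than at 0.2 µM in 4 of 4 such pairs, by 1.60, 1.28, 1.93 and 0.43.

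Across probes, which are not independent replicates, fold changes at 0.2 and 20 µM correlated at 0.598, against 0.250 simulated for unchanged groups that share 12 controls (covariance 0.0510 against 0.0146). Against own-array controls the correlation was 0.540 (covariance 0.0488). Those controls are different samples for each dose but come from the same near-identical sets, and no value was simulated for unchanged groups against them. The simulation drew the 12 controls as independent although they form near-identical sets, so 0.250 may be too low. Part or all of each excess may thus come from shared controls. The simulation also leaves out the likeness of the 0.2 and 20 µM samples that share a slide and a dye. For 2 and 20 µM the correlation was 0.443 (covariance 0.0380) and 0.412 with own-array controls. For 0.2 and 2 µM it was 0.486 (covariance 0.0357) and 0.465 with own-array controls.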

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

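Apart from the counts of splits, the tests of explanations in this part were chosen after the results were seen. Of 73 groups of 4 samples tested for a sample far from the others, 2 stood out (2.74%), where chance gives about 1 in 20. Both were juglone 2 µM replicate 3. There mtl-1 was 12.85 on the log2 scale against a mean of 11.28 in the other 3 samples (gap over range 0.839), and the first principal component was 148 against a mean of -35.3 (gap over range 0.861).

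Of 100 splits of the 20 µM and control samples 1, the real one, gave as many as the 80 probes called at 20 µM, and the highest other gave 15. These splits treat the 12 controls as independent samples, so they exclude chance only as far as that holds. The totals of 89 with 75th percentile scaling and 76 with slide as a term count partly other probes. Of the 80 probes, 67 still passed with that scaling, 80 with loess and 69 with slide as a term. These overlaps argue against normalization or slide as the whole cause of the calls. The scaling raised the median of all probes at 20 µM, which favours higher calls, so its total of 89 by itself decides nothing. Near-identical controls bear on the count, which was 0 with control sets averaged. The median SE was then 1.90 times as large and the median fold ratio 0.965, so the calls ended with a larger SE and little change in the folds. Averaging leaves 2 control samples, which raises the SE by itself. It also reuses the same controls with other weights, so it cannot show whether the repeated controls made the folds. What stays open is how many of the 80 would pass with separate control cultures; simulated unchanged groups with repeated controls gave a median of 2448.5 calls at 20 µM and 2414.5 at 0.2 µM, where the real count was 0, so that simulation overstates the calls in these data.

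For 20 against 2 µM, 5 of 35 splits gave at least 17 probes (highest other 3255), and for 20 against 0.2 µM 3 of 35 gave at least 33 (highest other 1757), so chance was not excluded for either. The latter splits take no account of the slide and dye that 0.2 and 20 µM samples share. On the 8 samples alone 0 probes passed with these as a block and 0 without it, so the 0 cannot be put down to the block. For the trend and for any dose, 2 of 100 splits each gave as many as the real 25 and 48 (highest others 975 and 576). Those splits also treat the 24 samples as independent although the controls form 2 near-identical sets, so chance is not excluded for either. With the sets averaged both counts were 0, but that fit holds only 2 control samples, so it decides nothing about chance. For 0.2 and 2 µM against control, with 0 calls, all 100 splits gave as many (highest others 2 and 1684), and for 2 against 0.2 µM all 35 did (highest other 2363). Every split gives at least 0 calls, so these decide nothing. Splits that call many times the real count point to a structure of the samples other than dose.

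Separately, 3 juglone samples, 1 per dose (0.2 µM replicate 2, 2 µM replicate 3 and 20 µM replicate 2), stood apart at 111, 148 and 144 on the first component. A low share of probes above the negative controls as the cause is argued against by 1 of the 3 lying above the median of the other samples. All 3 were Cy5, and 25% of the Cy5 samples stood apart, but that share counts near-identical controls. Other Cy5 juglone samples did not stand apart (-40.9, -50.2 and -31.5 in 0.2 µM replicate 4, 2 µM replicate 1 and 20 µM replicate 4). These values argue against dye alone. No Cy3 juglone sample stood apart, so a part played by dye stays open. Each dose had 1 such sample, and no biological explanation was tested.

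Juglone 2 µM replicate 4 differed from the 9 controls by at most 0.352, within the range among them. Its smallest difference, 0.235, was from the control on its own array. An unaffected culture and control RNA in this sample cannot be told apart, because either would resemble the controls. The sample was kept as labelled.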

How the results depend on the processing

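The alternatives that average control sets, leave out the 3 or 6 samples that stand apart, filter on the negative controls, use residual components or fit the 0.2 and 20 µM samples alone were chosen after seeing the data; the others were planned. Counts of probes stayed within 1.5 times in 267 cases and moved further in 136. Only the 42 list results that passed at the preset correlation were followed. Apart from the estimated correlation itself, each alternative was judged at the preset one. On that basis they kept direction and side of the threshold in 1750 cases, lost the threshold in 285 and turned direction in 22. With an estimated correlation 0, 0 and 1 lists passed at 0.2, 2 and 20 µM in the main fit, so the 1750 cases do not show that these results stand. Among named genes, 3294 cases kept their side of the threshold, 418 lost it, 1 turned direction and 38 came to pass. The 3294 include genes called in neither fit, whose direction was not compared. The cause was not tested unless stated. Dim probes limit what can be seen, since the offset compresses their folds and between 28.4% and 55.4% of probes exceeded the negative controls. By replicate number, no paired analysis was possible across all groups because the numbers follow accession order, and the labels pair no samples across doses. The values hint at pairs: 0.2 and 20 µM samples that share a slide and a dye had correlated deviations (0.242 to 0.730). On those 8 samples alone the count for 20 against 0.2 µM was 0, with slide and dye together as a block or without it. Among these samples that block is the same as the replicate number, so the fit with it was paired by number. Fewer samples were fitted there than in the main design, and the spread came from juglone samples alone. The shared array pairs 1 juglone sample with 1 control sample, and it was used as a block. The moderated variance with a trend does not enter camera, so it gives no list value.

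With control sets averaged, with or without juglone 2 µM replicate 4, the counts for 20 µM, 20 against 2 µM, 20 against 0.2 µM, the trend and any dose were all 0. Averaging leaves 2 control samples in place of 12. With the array as a fixed block these 5 counts were 0 as well, and with own-array controls the 20 µM count was 0. Without the 3 controls that stand apart the counts were 11 at 0.2 µM, 128 at 20 µM, 27 for 20 against 2 µM, 91 for the trend and 98 for any dose. This fit and the next count the 9 near-identical controls as 9 independent samples. Their median SD was 0.22, against 0.33 over the 12 controls, so higher counts here are no stronger evidence. Without the 6 samples that stand apart the counts were 37 at 0.2 µM, 11 at 2 µM, 149 at 20 µM, 35 for 20 against 2 µM, 15 for 20 against 0.2 µM and 160 for any dose. Collagen medians then turned to 0.031 at 0.2 µM and 0.089 at 2 µM, and ribosomal proteins at 20 µM to 0.052. Without the 3 juglone samples that stand apart, 19 probes passed for 20 against 0.2 µM and 4 for the trend. Medians at 2 µM were then 0.040 for collagens, 0.0086 for the mitochondrial respiratory chain, 0.040 for muscle markers and -0.013 for glycolysis, where camera's direction turned, and the median was 0.038 for ribosomal proteins at 20 µM.

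With the Cy3 samples alone the counts were 47 at 20 µM, 0 for the trend and 21 for any dose. Medians at 2 µM were 0.051 for the hypoxia response, 0.0084 for the respiratory chain, 0.062 for intestine markers, 0.070 for muscle markers and -0.0021 for glycolysis, where camera's direction turned. At 20 µM they were 0.0011 for innate immune effectors, again with camera's direction turned, and 0.013 for ribosomal proteins. With the Cy5 samples alone the counts were 1 at 0.2 µM, 1039 at 2 µM, 34 at 20 µM, 7 for 2 against 0.2 µM, 9 for 20 against 2 µM, 0 for 20 against 0.2 µM, 0 for the trend and 149 for any dose. The collagen median at 0.2 µM was 0.00075, and that of major sperm proteins at 20 µM was -0.045 with camera's direction turned. Each dye subset holds 2 samples per dose.

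Without background correction the counts were 1 at 0.2 µM, 2 at 2 µM and 28 for 20 against 2 µM. With loess they were 3 at 0.2 µM, 125 at 20 µM and 38 for the trend, and the ribosomal protein median at 20 µM turned to 0.019. With slide as a term they were 1 at 0.2 µM and 6 for 20 against 2 µM. With gene means they were 1 at 0.2 µM and 52 at 20 µM, where genes are counted in place of probes. With probes above background in all 24 samples, fewer probes were tested, and the counts were 25 at 20 µM, 1 for 20 against 2 µM, 5 for 20 against 0.2 µM and 5 for any dose. The deposited log2 table gave 6 at 2 µM, 44 at 20 µM, 1 for 2 against 0.2 µM, 10 for 20 against 2 µM, 5 for 20 against 0.2 µM, 5 for the trend and 27 for any dose, and gsr-1 at 20 µM was -0.17. At an adjusted p under 0.01 the counts were 49 at 20 µM, 7 for 20 against 2 µM, 15 for 20 against 0.2 µM and 4 for the trend, by construction. With array weights they were 0 for 20 against 2 µM and 13 for 20 against 0.2 µM. The trend called 50 probes with 75th percentile scaling, 15 without a filter, 11 without the dye term, 4 without the array block, 4 with neither, 44 with the negative control filter and 8 at 1.5-fold or more. With an estimated correlation the glutathione S-transferase list (median 0.22) and the UDP-glucuronosyltransferase list (median 0.15) no longer passed at 20 µM.

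With the first residual component as a covariate the counts were 997 at 0.2 µM, 295 at 2 µM, 1973 at 20 µM, 66 for 20 against 2 µM, 62 for 20 against 0.2 µM, 2167 for the trend and 1982 for any dose. With the first 2 they were 1956, 1397, 3228, 507, 143, 3073 and 3950 in the same order. Such components are orthogonal to the design, so the folds stay and the SE shrinks by construction.

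Leaving out 1 sample at a time gave 0 to 2 probes at 0.2 µM (2 without juglone 20 µM replicate 3 or control 3, 1 without control 12) and 44 to 251 at 20 µM (48 without replicate 1, 44 without replicate 2, 251 without replicate 4). For 20 against 2 µM the range was 7 to 60 (without 20 µM replicates 2, 3 and 4: 7, 11 and 60; without 2 µM replicates 1 and 4: 9 and 7). For 20 against 0.2 µM it was 3 to 57 (without 20 µM replicates 1, 3 and 4: 21, 19 and 57; without 0.2 µM replicates 1, 2 and 3: 11, 20 and 3; without control 2, 4, 8 or 10: 21 each). For the trend it was 3 to 94. The trend lay within 1.5 times of 25 only without 0.2 µM replicate 3, 2 µM replicate 3 or control 12. It was 3 without 20 µM replicate 3 and 94 without replicate 4. For any dose it was 28 to 102 (30, 30, 28 and 102 without 20 µM replicates 1 to 4). Medians ranged from -0.35 to 0.075 for major sperm proteins at 20 µM (highest without replicate 3), -0.20 to 0.023 for ribosomal proteins at 20 µM (highest without replicate 2), -0.23 to 0.030 for collagens at 2 µM and -0.71 to 0.0073 for muscle markers at 2 µM (highest without replicate 3 for both).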

Other observations

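The genes named in this part and the comparison without control samples were chosen after the data were seen. Several further genes passed in the planned comparison at 20 µM. Other members of the SKN-1 and phase II list were sdz-8, at 3.39 ± 0.55 (SE), gst-5 at 2.09 ± 0.36, nit-1 at 1.84 ± 0.33, gst-12 at 1.78 ± 0.34 and gst-14 at 1.16 ± 0.24. The gene wdr-23, whose product represses SKN-1, rose by 0.91 ± 0.18 (adjusted p = 0.028, 3 of 4 samples higher than on the same array) on 1 of 5 probes, and the other 4 went the same way without passing. The nuclear receptor genes nhr-182 and nhr-237 and the predicted sugar transporter gene swt-2 also passed. The rise was 0.73 ± 0.14 for nhr-182 on 1 of 3 probes, and 1 of the others went the opposite way without passing. In controls nhr-237 and swt-2 exceeded the negative controls in 0 of 12 samples, and they were at least 1.55-fold (adjusted p = 0.029) and at least 2.03-fold (adjusted p = 0.00086) higher. None of these calls held with averaged control sets, where 0 of the 80 probes passed.

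Some gene lists had loadings far from the middle on the first component, which the samples that stood apart in part define. Only selected lists are given, and no list was tested between those samples and the others. The median member of the vitellogenins lay at percentile 0.576 of the loadings over all genes (1 probe each), that of muscle markers at 6.14 and that of trehalose, glycogen and glycolysis genes at 8.98, all on the side lower in those samples. Innate immune effectors lay at 74.2 and osmotic stress response genes at 88.5, on the higher side. Other lists lay near the middle, such as neuron markers at 47.5 and C-type lectins at 44.6. The samples that stood apart also had high levels of 2 antimicrobial peptide genes. In the samples at 0.2, 2 and 20 µM (replicates 2, 3 and 2), nlp-29 was 12.81, 13.62 and 14.57 on the log2 scale, against 9.57 to 11.56 in the 12 controls. In the same samples cnc-4 was 12.70, 13.74 and 15.15, against 9.78 to 11.14 in controls. High peptide gene levels were not restricted to them, with cnc-4 at 13.00, 13.85 and 12.42 in the other 3 samples at 20 µM.

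A comparison that uses no control sample set the list means of the 4 samples at 20 µM against the 8 at lower doses. For SKN-1 and phase II targets the difference was 1.23 on the log2 scale, 4 of 4 samples at 20 µM lay above the other 8, and the exact permutation p over both directions was 0.0020, the smallest that 495 splits can give. Adjusted over the 44 lists it was 0.0889. That is the lowest value a single list at the smallest p can reach over 44 lists, so failing the threshold of 0.05 says nothing here. The hypothesis that this list may differ between doses independently of the controls is neither shown nor excluded.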
